A study of Mus musculus with 16 samples.

How the data were processed

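RNA from 16 mouse lung tumors was sequenced, 9 labelled Max null and 7 labelled Max wild-type, on a mixed 129/SvJ and C57BL/6 background. Per the labels' protocols, gene deletion followed instillation of adenovirus carrying CMV-driven Cre recombinase into the trachea, RNA was extracted with TRIZOL, and libraries were prepared from total RNA with an Ultra RNA kit for Illumina. RP is a name commonly used for mice with conditional Rb1 and Trp53 alleles, a model of small cell lung cancer; the labels do not spell the letters out.

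The deposited files hold counts, 1 whole number of reads per gene symbol for each of 23284 symbols, in 1 file per tumor. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.12, TopHat and HTSeq 0.6.1, and the mouse build mm9, with no role or order. The gene annotation, the strand setting and any filter are not given in the sources used here. Each of the 16 files ends with the totals HTSeq gives for reads that fell in no gene, in more than 1 gene or at more than 1 place in the genome. These totals stayed out of library sizes and tests. They took 29.2% to 32.9% of the reads in the 9 files labelled Max null and 32.8% to 45.7% in the 7 labelled Max wild-type. Reads aligned to more than 1 place belong to no gene in such counts, so genes with near-identical copies (ribosomal protein genes with processed pseudogenes, clustered histone genes) are uncertain in level.

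Reads in genes ranged from 8.66 to 15.11 M per tumor. Counting error is therefore small against the spread between tumors for genes above a few CPM (counts per M reads in genes), and it dominates for genes near 0. Among all pairs of libraries the smallest chi-square of the counts was 32.8 per degree of freedom and the highest correlation of log2 CPM was 0.963, so no pair agreed within sampling noise and each was counted as 1 sample.

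Groups were taken from the labels. The labels do not say that the tumors came from separate mice, so p-values measure the spread between these 16 samples. The comparison, its test, the alternative settings, 39 gene lists and the rule for naming genes were chosen before the data were examined. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM factors, after edgeR's filter on low counts (filterByExpr with the groups), which kept 14825 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and a further count took genes with a fitted log2 difference of at least 1. Differences are Max null minus Max wild-type. The SE of a log2 difference was computed as its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and principal components were taken from log2 CPM with a prior count of 2.

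Each gene list with at least 3 tested members (37 of the 39) was tested against the other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Fry's directional p asks whether the members of a list move on balance one way and does not compare them with other genes. Calls were counted over all genes and also adjusted over the list alone. The mean log2 CPM of each list per tumor and the library properties were compared with a two-sided permutation test, exact over all 11440 splits of 16 tumors into 9 and 7, with Benjamini-Hochberg adjustment over the 37 lists or the 8 properties.

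The genes named were chosen by a fixed rule. It takes Max, Rb1, Trp53 and the MYC, MAX and MLX family. Among called genes with a mean of at least 1 CPM, it takes the 10 with the smallest p and the 5 with the largest change in each direction. For each list it takes up to 4 called members with the smallest p, or, where none was called, up to 2 members with the highest mean. Symbols of unnamed gene models were counted and not named. Of the 127 genes, 4 share at least 20% of their exon bases with another counted gene in the reference annotation: Dph1 with Ovca2 on the same strand, and Sgsh with Card14, Tsr1 with Srr and Ydjc with Ube2l3 on opposite strands. Where the annotation used for counting held the same overlap, reads in both genes entered neither count. Where it did not, reads of the partner may be included. A strand setting, also not stated, could separate only the pairs on opposite strands. These genes are therefore uncertain. Other genes named in the text were chosen after their values were seen and are marked as such. Single results for some genes are not reported here.

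The alternatives were other scalings (DESeq2-style and upper-quartile factors), DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, a stricter filter (at least 5 CPM in at least 7 samples), the tumor number as a block, 3 surrogate variables (sva 3.50.0), the first principal component of 178 marker genes of other cell types as a covariate, the mean of 4 Y-linked genes as a covariate, and leaving out each tumor. Added after the data had been seen were fits without wild-type tumors 2, 4 and 7, which had the highest shares of multiply aligned reads, with that share as a covariate, and with a correction for transcript length and GC content. For the correction, each gene's deviation from its mean was smoothed per library (loess, span 0.3) on log2 transcript length and then on GC content, and the smooth was subtracted through the model's offsets. Also added were fits leaving out each of the 35 sets of 3 wild-type tumors and a scan of families of gene symbols.

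Transcript lengths, GC content and gene order came from GENCODE M21 and RefSeq tables for GRCm38, matched by symbol or older symbol for 98.0% of the symbols. Since the files are on mm9, these tables served only for names, lengths and which genes neighbour each other, and coordinates are not reported. The procedure was tested on simulated counts for these 9 and 7 libraries over 14723 genes. It recovered 37% of 100 genes changed 2-fold and 85% of 100 genes changed 4-fold, with 4 of 126 calls false and 0 of wrong sign. DESeq2 recovered 54% and 92% of the same genes. Of 20 unchanged simulated lists 0 were called, and 1 changed list was called. Each gene was drawn independently and with no library bias, so these figures do not cover lists whose members vary together. With the real counts, 86 of 100 splits of the tumors gave at least the 7 lists called in the main fit. Figures were drawn with matplotlib.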

Results

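Gene expression was measured by RNA sequencing in 9 lung tumors labelled Max null and 7 labelled Max wild-type from mice of the RP model. MAX is the obligate DNA-binding partner of MYC, MYCL and MYCN. It is also a partner of the MXD proteins, MNT and MGA, which mostly repress transcription. The series makes 1 comparison, which asks how the transcriptome of these tumors differs when Max has been deleted. Reads in genes, in M (megareads), were 12.5, 9.81, 11.1, 15.11, 8.66, 13.5, 13.3, 13.96 and 12.9 for null tumors 1 to 9 and 13.2, 9.15, 10.8, 9.65, 11.4, 11.5 and 9.93 for wild-type tumors 1 to 7. The groups did not differ in this depth by an exact permutation test (12.3 ± 2.07 M, SD, n = 9, against 10.8 ± 1.38 M, n = 7; p = 0.12).

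Max itself was not lower in the tumors labelled null. It measured 76.5, 75.9, 83.5, 78.1, 77.5, 66.6, 75.8, 72.0 and 64.2 CPM in null tumors 1 to 9 and 52.4, 58.4, 71.6, 67.7, 66.1, 75.9 and 68.6 CPM in wild-type tumors 1 to 7. The log2 difference was 0.18 ± 0.11 (SE, adjusted p = 0.281). The count covers the whole gene and the labels do not say which part was removed, so it cannot check the genotype, and each direction below is drawn between groups as labelled. Rb1 (log2 difference -0.54 ± 0.30, adjusted p = 0.212) and Trp53 (-0.66 ± 0.26, adjusted p = 0.083) did not pass the threshold.

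Stag3, which encodes a meiosis-specific cohesin subunit, had the smallest p of the comparison. It measured 198 ± 37.5 CPM in tumors labelled null (SD, n = 9) and 2.76 ± 4.35 CPM in tumors labelled wild-type (n = 7), a log2 difference of 6.14 ± 0.73 (SE, adjusted p = 0.000843). Its lowest null tumor, at 148 CPM, lay far above its highest wild-type tumor, at 11.9 CPM. Mei1, needed for meiotic double-strand breaks, rose by 5.04 ± 0.68 on the log2 scale (8.24 ± 5.22 against 0.241 ± 0.216 CPM, adjusted p = 0.00144), and was higher in 9 of 9 null tumors than in any wild-type tumor. Prr19, a meiotic recombination factor, rose by 4.25 ± 0.62 (adjusted p = 0.00172), and Rbm46, an RNA-binding protein of germ cells, by 4.83 ± 0.90 (adjusted p = 0.0043). The other genes with the largest rise were Itm2a and Cpn1, at 4.35 ± 1.23 and 4.26 ± 1.31, which varied widely between null tumors (SD 149 and 32.7 CPM). Itm2a was 2.18 and not called without null tumor 5, and Cpn1 lost its call in 7 fits without 1 tumor and with DESeq2. Rbm46 (4.73), Itm2a (5.15) and Cpn1 (4.87) did not pass without wild-type tumors 2, 4 and 7.

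**Figure D1:**
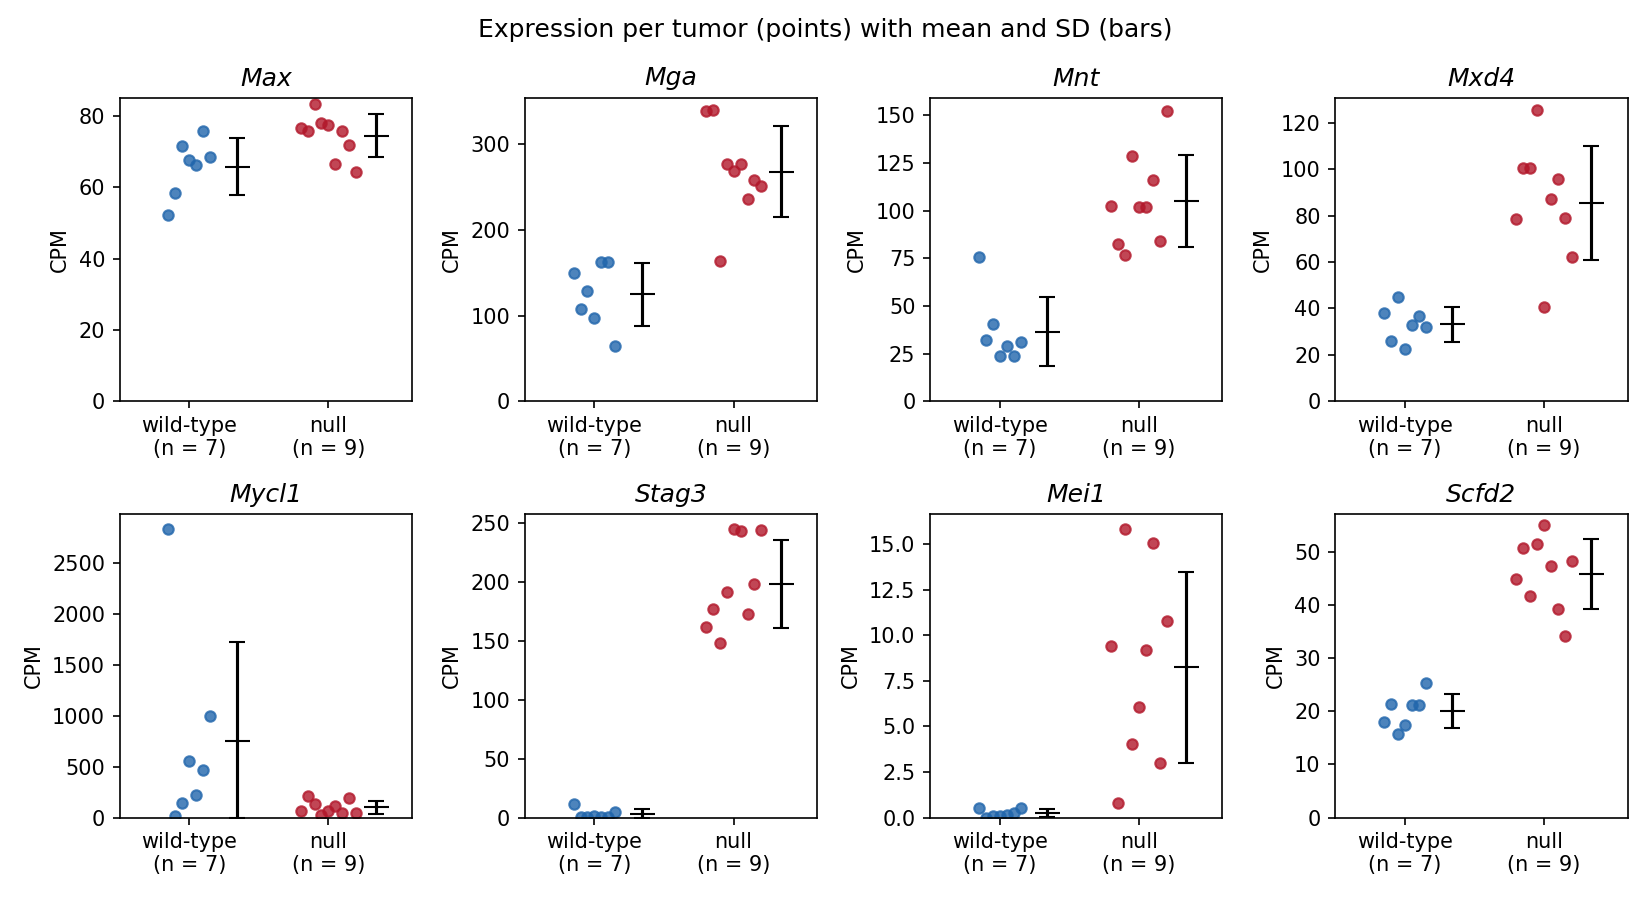
Expression in CPM (vertical axes, each from 0) of 8 genes in each tumor, as points by labelled genotype, with the group mean and SD as bars (lower bars end at 0). Max overlaps between the groups, while Mga, Mnt, Stag3, Mei1 and Scfd2 are higher in 9 of 9 null tumors and Mxd4 in 8 of 9 than in any wild-type tumor, and Mycl (Mycl1) reaches 2832 CPM in 1 wild-type tumor.

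Of the 24 tested genes of a fixed list of germline and meiosis genes, 4 rose, 2 fell and 18 did not pass the test over all genes (4 and 4 adjusted over the list alone). Those that rose were Stag3, Mei1, Tdrd1 (4.01 ± 1.17, adjusted p = 0.0302), of the piRNA pathway, and Cpeb1, a regulator of oocyte mRNA translation (2.40 ± 0.40, adjusted p = 0.00278). The DNA repair gene Rad51c fell by 0.86 ± 0.23 (adjusted p = 0.0202) and Hsf2bp, a partner of BRCA2 in meiosis, by 1.56 ± 0.50 (adjusted p = 0.0427). The mean log2 CPM of the list per tumor was 2.48 ± 0.260 in null and 1.83 ± 0.315 in wild-type tumors (SD, n = 9 and 7; exact permutation p = 0.000612, adjusted over 37 lists 0.0226). Its median log2 difference was 0.12, with 13 members above 0 and 11 below. Against other genes the list did not pass camera (adjusted p = 0.241). In the fit without wild-type tumors 2, 4 and 7, 3 members were called, Stag3, Mei1 and Cpeb1, all higher. Tdrd1, Hsf2bp and Rad51c (-0.84) were not called there.

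Genes of the network around MAX changed in both directions. Mnt (105 ± 24.2 against 36.6 ± 18.1 CPM), Mxd4 (85.5 ± 24.5 against 33.3 ± 7.52 CPM) and Mga (268 ± 53.1 against 125 ± 36.7 CPM), each encoding a repressive partner of MAX, rose by 1.52 ± 0.24, 1.36 ± 0.21 and 1.10 ± 0.20 on the log2 scale (adjusted p = 0.00213, 0.00213 and 0.00347). None of these passed with the multiply aligned share as a covariate, where they were 1.27, 1.11 and 0.57. That share did not overlap between the groups, so the fit cannot separate it from the labelled genotype. Mlxip, which encodes a partner of MLX, rose by 0.56 ± 0.13 (adjusted p = 0.0109, 0.095 without wild-type tumors 2, 4 and 7, where it was 0.47, and 0.387 after the length and GC correction, where it was 0.16, in a range over its alternatives from 0.000384 with DESeq2 to 0.387). Mycl, the MYC family member frequently amplified in small cell lung cancer and listed in the files as Mycl1, fell by 2.92 ± 0.70 (adjusted p = 0.0135), from 749 ± 974 CPM in wild-type tumors to 99.2 ± 67.6 CPM in null tumors. Its wild-type values were 2832, 18.7, 146, 556, 226, 466 and 999 CPM, and without wild-type tumor 1 the log2 difference was -2.01. Mycl did not pass with voom (adjusted p = 0.0804), with surrogate variables (0.372) or with the multiply aligned share as a covariate (0.183, log2 difference -3.16), in a range over its alternatives from 0.000236 (DESeq2) to 0.372. Of the 13 family members tested, 4 rose, 1 fell and 8 did not pass (4 and 2 adjusted over the list alone), among them Myc (-0.36 ± 0.32, adjusted p = 0.455) and Mycn (0.61 ± 0.68, adjusted p = 0.562). The list did not pass camera (adjusted p = 0.159).

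Over all genes tested, 2378 of 14825 passed the threshold, 1097 higher and 1281 lower in tumors labelled null, and 1176 of them changed at least 2-fold (577 higher, 599 lower). In 232 tested genes (1.56%) the groups did not overlap, where chance gives 0.0175%, and 230 of these were called. Besides the genes above, the smallest p among higher genes belonged to Scfd2, Mrm1, Slc9a7, Uprt, Wdr81, Dph1 and Ydjc, with log2 differences from 1.12 (Mrm1, a mitochondrial rRNA methyltransferase) to 3.28 (Uprt). Dph1 starts diphthamide synthesis on elongation factor 2. It measured 19.6 ± 3.69 against 4.29 ± 1.95 CPM and shares exons with Ovca2.

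The genes that fell with the smallest p were Eif4ebp3, Fam133b, Ncan, Hist1h2bc, Cryba2, Taf1d, Fgf21, Irak1bp1, Strn3 and Onecut2. Onecut2, a transcription factor of neural and endocrine lineages, fell by 2.89 ± 0.44 (16.6 ± 11.9 against 123 ± 58.8 CPM, adjusted p = 0.00213). Eif4ebp3, a repressor of cap-dependent translation, fell by 1.47 ± 0.18 (adjusted p = 0.000843). Ncan, a neural proteoglycan, fell by 2.72 ± 0.37 (adjusted p = 0.00145). The 5 largest falls were those of Ppp1r17, the glucagon receptor gene Gcgr, Lgi1, Hoxb9 and Krt17, from -4.75 to -4.33, all at under 5 CPM on average in null tumors. Of these, 3 lost their call without 1 tumor: Gcgr was -1.68 without wild-type tumor 1, Krt17 -2.24 without wild-type tumor 4 and Hoxb9 -3.04 without wild-type tumor 6. Ppp1r17 (-3.61) and Krt17 (-1.54) did not pass without wild-type tumors 2, 4 and 7.

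These counts depended on a few wild-type libraries. Without wild-type tumor 4 the number of called genes was 1471, without wild-type tumor 7 it was 1555, and without wild-type tumors 2, 4 and 7 it was 256 (123 higher, 133 lower), of which 238 were also called with all 16 tumors, 238 in the same direction. Those 238 included Stag3, Mei1, Mnt, Mxd4, Mga and Mycl, and all 20 genes with the smallest p named above. With fewer samples in this fit, a call lost there does not by itself show that a gene's difference rests on those tumors.

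The libraries themselves differed by group. Reads aligned to more than 1 place made up 10.8 ± 0.818% of reads in null tumors (range 9.17% to 11.78%) and 16.01 ± 3.96% in wild-type tumors (12.26% to 22.2%), with no overlap (exact permutation p = 8.74e-05, the smallest that 11440 splits can give, adjusted over 8 properties 0.000699). The share was 16.01%, 20.8% and 22.2% in wild-type tumors 2, 4 and 7. The unprocessed rRNA gene Rn45s took 0.270 ± 0.211% against 0.831 ± 0.897% of reads in genes (exact permutation p = 0.0316, adjusted 0.0421). Across genes within a library, the correlation of expression relative to the mean over tumors with transcript length averaged 0.171 ± 0.109 in null tumors and -0.147 ± 0.249 in wild-type tumors (exact permutation p = 0.00245, adjusted 0.0098). It was lowest in wild-type tumors 7 (-0.523) and 4 (-0.407), while null tumor 3 had -0.096 and wild-type tumors 1 and 5 had 0.186 and 0.064. Genes called higher had a median transcript length of 4964 bases and genes called lower 2294 bases. With the multiply aligned share as a covariate 10 genes were called, 8 higher (Maged2, Scfd2, Stambpl1, Smyd5, Stag3, Nme2, Mei1 and Prr19) and 2 lower (Prpf39 and Strn3). Those outside the fixed rule were named after their values were seen. Since the share did not overlap between the groups, this fit cannot separate it from the labelled genotype. The SE of Stag3 was 1.04 there, against 0.73 in the main fit. A call lost in this fit does not show that the share was its cause.

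**Figure D2:**
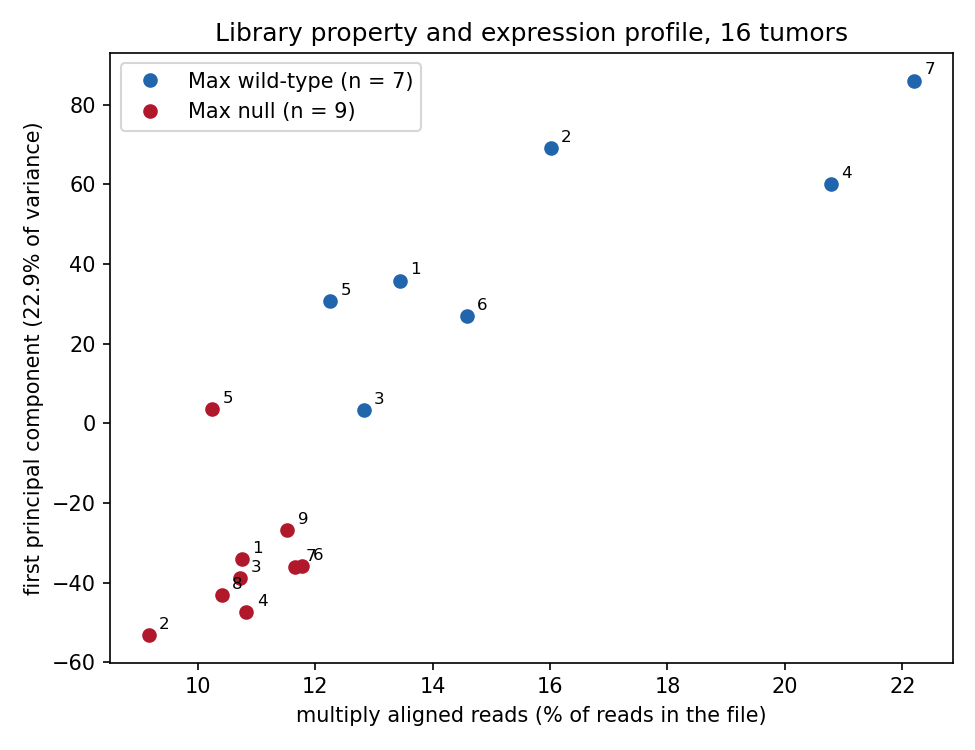
Share of multiply aligned reads in percent of reads in the file (horizontal axis) against the first principal component of log2 CPM, 22.9% of the variance (vertical axis), for 16 tumors numbered within their group. Wild-type tumors lie at 12.26% or above and null tumors at 11.78% or below, and wild-type tumors 2, 4 and 7 have the highest values on both axes.

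Genes for building ribosomes and genes for their protein parts gave medians of opposite sign. Of 49 tested ribosome biogenesis factors, 13 rose, 4 fell and 32 did not pass (14 and 7 adjusted over the list alone), with Rrp12 (1.28 ± 0.23), Tsr1 (1.02 ± 0.16), the RNA polymerase I subunit gene Polr1a (0.99 ± 0.18) and Rrp9 (0.89 ± 0.18) leading. The median of the list was 0.10 and it passed camera as higher (adjusted p = 0.0289; adjusted p = 0.849 with an estimated correlation). Its mean level per tumor did not pass adjustment (exact permutation p = 0.0356, adjusted 0.165). Cytosolic ribosomal protein genes had a median of -0.79, with 44 of 44 below 0 but only 8 called, all lower, among them Rpl24, Rps25, Rps27 and Rps6 (9 adjusted over the list alone; camera adjusted p = 4.99e-05; adjusted p = 0.849 with an estimated correlation). Of 37 respiratory chain and ATP synthase genes, 10 fell, led by Cox5a, Ndufv2, Ndufa2 and Cox7a2, and 27 did not pass (17 lower adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.000223; adjusted p = 0.849 with an estimated correlation). Mean levels per tumor did not pass adjustment for ribosomal proteins (8.86 ± 0.177 against 9.35 ± 0.931 log2 CPM, exact permutation p = 0.112) or the respiratory chain (p = 0.031, adjusted 0.165). Without wild-type tumors 2, 4 and 7, with the highest shares of multiply aligned reads, the medians were 0.07 and -0.03 with 0 genes called in either list, while 5 ribosome biogenesis factors were called higher, Rrp12, Tsr1, Polr1a and Rrp9, called with all 16 tumors, and Grwd1, not called there (named after its value was seen). With the multiply aligned share as a covariate both medians turned positive, at 0.60 and 0.28, in a fit that cannot separate the share from the labelled genotype.

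Among 23 sterol synthesis genes, 6 rose, 0 fell and 17 did not pass (7 and 2 adjusted over the list alone), with Lss (adjusted p = 0.00781) first, then Dhcr7 at 0.82 ± 0.21 and the sterol carrier gene Stard4 at 1.28 ± 0.35 (list median 0.28, camera adjusted p = 0.0285; adjusted p = 0.849 with an estimated correlation). Their mean per tumor was 5.46 ± 0.246 against 5.08 ± 0.134 log2 CPM (exact permutation p = 0.00262, adjusted 0.0485). Among 23 glycolysis genes, 5 rose, 0 fell and 18 did not pass (5 and 0 adjusted over the list alone): hexokinases Hk2 (1.85 ± 0.42) and Hk1 (0.62 ± 0.16), the lactate transporter gene Slc16a1 (0.96 ± 0.25), the glucose transporter gene Slc2a3 (2.10 ± 0.54) and Pdk1 (0.69 ± 0.22), with a list median of 0.41 (camera adjusted p = 0.0289; adjusted p = 0.849 with an estimated correlation). The mean per tumor of the glycolysis list did not pass (exact permutation p = 0.0867, adjusted 0.254). Without wild-type tumors 2, 4 and 7, 1 glycolysis gene was called, Slc16a1 (1.22), and the list passed camera at the preset correlation (list median 0.48, adjusted p = 0.0073). There, 0 sterol synthesis genes were called, and that list did not pass (list median 0.26, camera adjusted p = 0.0756).

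Nucleotide and one-carbon enzymes gave mixed counts. In the list of 30 serine, glycine and one-carbon genes, 6 rose, 1 fell and 23 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.159), with methionine synthase Mtr at 1.12 ± 0.22 and Mthfd1 at 1.01 ± 0.20. Of 29 purine and pyrimidine synthesis genes, 3 rose, 2 fell and 24 did not pass (3 and 2 adjusted over the list alone; list median -0.01, mean 0.04, camera adjusted p = 0.556). Cad, which starts pyrimidine synthesis, rose by 1.38 ± 0.22, and Atic, which ends purine synthesis, by 0.87 ± 0.21, while thymidylate kinase Dtymk fell by 0.88 ± 0.19. Cad (1.22) and Atic (0.74) were called without wild-type tumors 2, 4 and 7, Dtymk (-0.66) was not, and 0 one-carbon genes passed, with Mthfd1 at 0.91 and Mtr at 0.85.

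**Figure D3:**
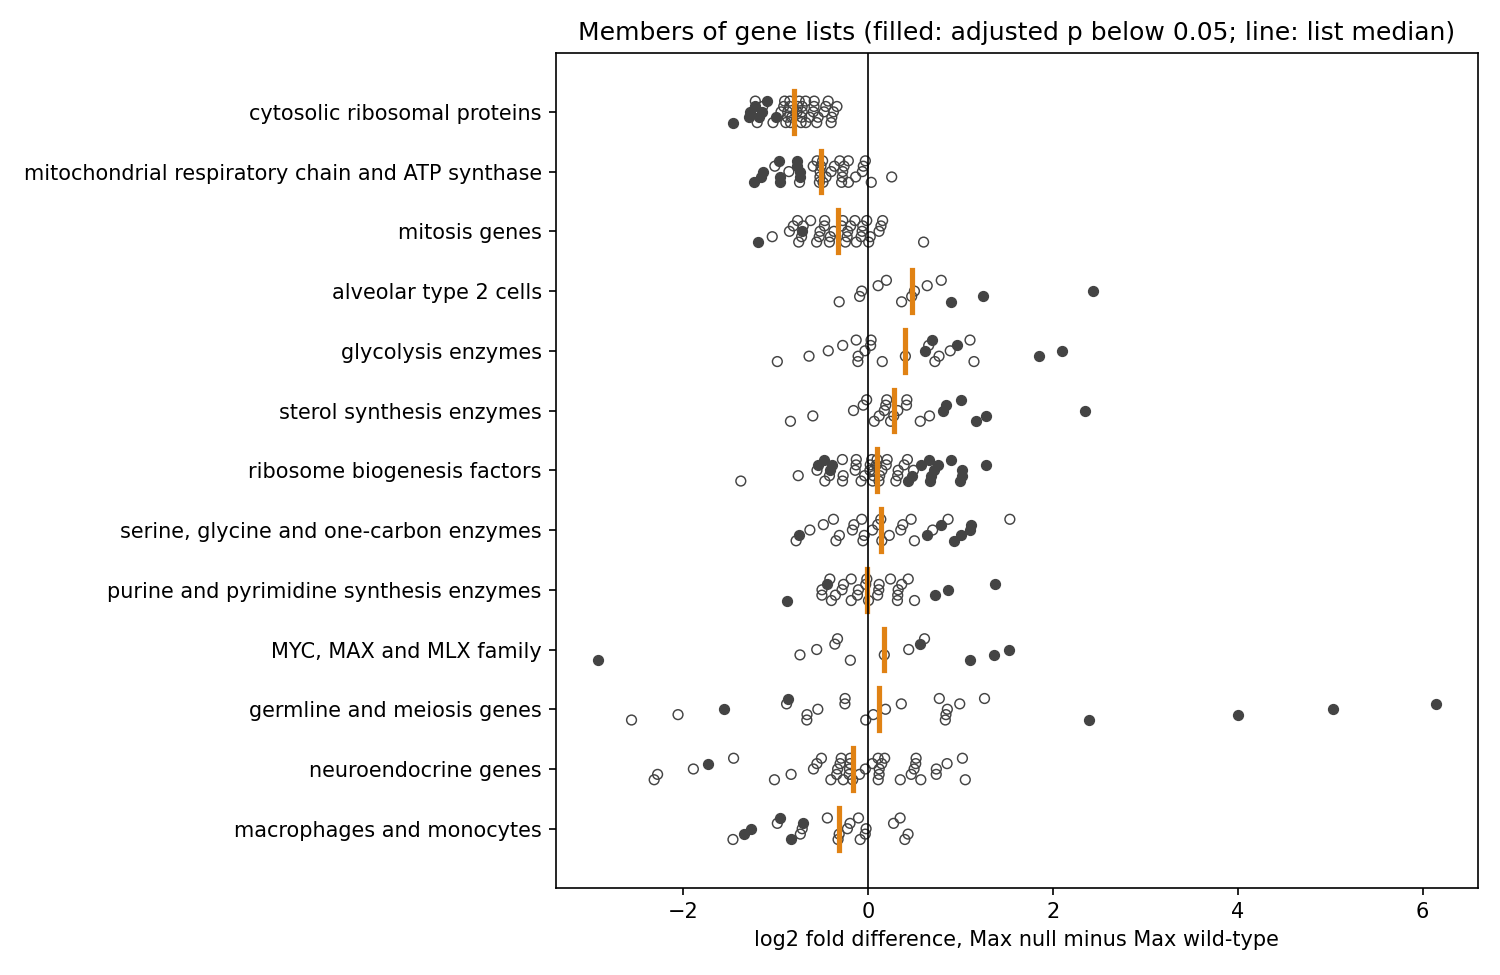
Log2 fold difference, Max null minus Max wild-type (horizontal axis), of each tested member of 13 gene lists, filled where the adjusted p was below 0.05, with the list median as a line. All 44 ribosomal protein genes lie below 0 with a median of -0.79, a median that is 0.07 without wild-type tumors 2, 4 and 7, and Stag3 lies farthest to the right at 6.14.

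Of 41 neuroendocrine genes 1 was called, Nfib, an oncogene of small cell lung cancer, which fell by 1.73 ± 0.41 (377 ± 224 against 1253 ± 982 CPM, adjusted p = 0.0126); the other 40 did not pass, the list median was -0.16 and camera gave an adjusted p of 0.835. Among 5 tested NEUROD1-related genes, Hes6 and Neurod4 fell, by 1.03 ± 0.22 and 2.96 ± 0.88 (2 lower adjusted over the list alone, camera adjusted p = 0.176). Of 31 Notch pathway and non-neuroendocrine genes, the ligand gene Jag1, the receptor gene Notch3 and the neuronal repressor gene Rest rose, by 1.37 ± 0.33, 1.16 ± 0.32 and 1.35 ± 0.40, Ctgf fell and 27 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.241). Among 36 mitosis genes, Bub3 and Cdc25c fell and 34 did not pass (0 adjusted over the list alone), with a list median of -0.33 (camera adjusted p = 0.00916; adjusted p = 0.849 with an estimated correlation). Without wild-type tumors 2, 4 and 7, Nfib (-1.85 ± 0.47, adjusted p = 0.0617, range over its alternatives 0.000862 with DESeq2 to 0.217 with the multiply aligned covariate) and the mitosis list (median -0.11, camera adjusted p = 0.139) did not pass. The same was true of every other called gene of this paragraph: Hes6 (-0.92), Neurod4 (-3.40), Jag1 (1.39), Notch3 (0.88), Rest (1.79), Ctgf (-1.09), Bub3 (-0.36) and Cdc25c (-0.76).

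Markers of other lung cells were called in both directions. Of 13 alveolar type 2 cell genes, Abca3 (1.25 ± 0.22), Hc (2.43 ± 0.57) and Lpcat1 (0.89 ± 0.26) rose and 10 did not pass (3 adjusted over the list alone; list median 0.47, camera adjusted p = 0.0139; adjusted p = 0.849 with an estimated correlation). Their mean per tumor did not pass (6.55 ± 0.615 against 5.52 ± 1.59 log2 CPM, exact permutation p = 0.0845, adjusted 0.254), with wild-type tumors 1 and 2 lowest, at 2.53 and 4.30. Abca3 (0.92) was called without wild-type tumors 2, 4 and 7, Hc (2.25) and Lpcat1 (0.50) were not (list median 0.32, camera adjusted p = 0.017 at the preset correlation). Of 22 macrophage and monocyte genes, 5 fell, among them the complement genes C1qa, C1qb and C1qc, and 17 did not pass (5 adjusted over the list alone; camera adjusted p = 0.115), with 0 called without wild-type tumors 2, 4 and 7, where C1qa was -0.76, C1qb -1.14 and C1qc -1.08. C1qa also lost its call in 6 fits without 1 tumor. Fry called 3 lists at an adjusted p of 0.0213: the MYC, MAX and MLX family, with a median of 0.18, adipocyte genes (3 tested, median -0.43), and thymus and lymph node genes (4 tested, median -1.14). None passed camera (adjusted p = 0.159, 0.36 and 0.281; adjusted p = 0.849 for each with an estimated correlation). Without wild-type tumors 2, 4 and 7 the adipocyte median was 0.67 (6 tested, 0 called) and the thymus and lymph node median -0.54 (4 tested, 0 called). The median of the MYC, MAX and MLX family was 0.16 there (13 tested, 3 higher, 1 lower).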

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

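No test in this part was chosen after the result was seen. Of 170 values checked for a library far from the others of its group, 13 stood out, where chance gives about 8.5, so single outlying values carry little weight.

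Among wild-type tumors, Dph1 was lowest in tumor 6, at 0.902 CPM against 3.39 to 6.97 CPM in the others. Rn45s took 2.74% of reads in genes in tumor 4, against 0.174% to 1.12%. The mean of the mitosis list was 6.01 log2 CPM in tumor 3, against 6.86 to 7.50. The mean of the NEUROD1 list was 3.37 log2 CPM in tumor 2, against 5.48 to 6.63.

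Among tumors labelled null, tumor 3 stood out in 4 values. Its Mga was 163 CPM, against 236.5 to 340 CPM in the other 8, and its Irak1bp1 was 7.265 CPM, against 12.1 to 17.4 CPM. Its Rn45s share was 0.791%, against 0.121% to 0.327%, and its mean of the neutrophil list was 3.42 log2 CPM, against 1.62 to 2.36. Null tumor 5 was lowest in Mlx (27.4 CPM, against 38.0 to 50.7 CPM), in the mean of the epithelial-mesenchymal transition list (4.69 log2 CPM, against 5.58 to 6.17) and in the mean of the lysosome and autophagy list (6.09 log2 CPM, against 6.41 to 6.73). The epithelial-mesenchymal transition list includes the epithelial genes Krt8 and Cdh1, so its mean gives no direction of transition. Null tumor 9 had the highest mean of immediate early genes, at 5.82 log2 CPM against 4.49 to 5.05. Null tumor 4 had the lowest mean of tuft-cell genes, at 2.27 log2 CPM against 2.78 to 3.13.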

How the results depend on the processing

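The fits without wild-type tumors 2, 4 and 7, with the multiply aligned share and with the length and GC correction were chosen after the result was seen. The number of called genes (2378) was within 1.5 times under both other scalings, voom, both other filters, the marker and sex-gene covariates and the length and GC correction (1648 to 2741). DESeq2 called 3612 (2014 lower, 1839 at least 2-fold). Surrogate variables left 519 (296 higher, 223 lower, 279 at least 2-fold). Without wild-type tumors 2, 4 and 7 there were 256 (123 higher, 133 lower, 173 at least 2-fold) and 3 lists. These lists were glycolysis (camera adjusted p = 0.0073 at the preset correlation), alveolar type 2 cell and ribosome biogenesis genes (0.017 each). The multiply aligned share as covariate, which does not overlap between the groups, left 10 (8 higher, 2 lower, 8 at least 2-fold). Leaving out 1 tumor gave 1471 to 3033 genes, 679 to 1463 higher, 792 to 1570 lower, 760 to 1504 at least 2-fold and 2 to 9 lists, and Max at 0.14 to 0.22. Max was 0.35 after the length and GC correction (adjusted p = 0.0511; 0.0511 to 0.617 over its alternatives). The lowest counts came without wild-type tumor 4 or 7, the highest without wild-type tumor 1; lists were 2 without wild-type tumor 2 and 4 without wild-type tumor 1. Lower genes were 826, 831 and 837 without null tumors 2, 6 and 7. Of 35 sets of 3 wild-type tumors left out, counts ran from 256 to 3619 with a median of 1518, and 1 set, tumors 2, 4 and 7, was that low. Lists were 0 with an estimated correlation and 3 with fry. The tumor number as a replicate block, on 14 tumors with 6 residual degrees of freedom, left 278 (190 higher, 88 lower, 257 at least 2-fold); same-numbered tumors deviated together by over 0.1 in 2 of 7 pairs (-0.17 to 0.237) and 1 of 7 null tumors correlated best with its own number, so the numbers do not pair the tumors. Called single genes kept direction except with the multiply aligned share, where 6 turned: Krt17 0.10, Rpl24 0.30, Rps25 0.16, Ndufv2 0.14, Ndufa2 0.23 and Cox7a2 0.24. Of single genes not called, 16 changed sign in some fit, Mycn among them (-0.14 to 1.05 over left-out tumors). Of 126 values for single genes, 90 were weaker with the multiply aligned share, 62 without wild-type tumors 2, 4 and 7, 61 with the block, 56 with surrogate variables, 21 with the length and GC correction and 19 with voom. Apart from fewer samples, the causes were not tested. Depth limits genes below about 1 CPM.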

Other observations

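Tests without wild-type tumors 2, 4 and 7 and tests with the length and GC correction were chosen only after the result was seen. The same holds for the test of Mycl without 1 tumor, the scan of gene symbols and the window of the 6 genes nearest Mycl.

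Immune and stress genes gave small sets of calls. The neutrophil receptor gene Cxcr2 fell by 1.46 ± 0.30 (12.1 ± 2.29 against 33.4 ± 21.7 CPM, edgeR adjusted p = 0.00651), the only call among 10 neutrophil genes (list median -1.06, camera adjusted p = 0.0518), and the T-cell kinase gene Lck fell by 1.31 ± 0.34, the only call among 11 T and NK cell genes. Cxcr2 (-0.72) and Lck did not pass without wild-type tumors 2, 4 and 7, nor did Ddit3 (-1.10), Slc7a5 (0.74), Sesn2, Cth, Map1lc3a (-0.21), Naglu (0.81), Muc5b (2.46), Sdc1 (1.05), Rpa2 (-0.77) or Rfc3 (-0.52). In the 23 tested ATF4 target and amino acid stress genes, Fgf21 (-2.20 ± 0.33), Ddit3 (-1.30 ± 0.27) and Atf4 itself (-0.72 ± 0.18) fell while the amino acid transporter gene Slc7a5 (1.06 ± 0.33), Sesn2 (0.72 ± 0.24) and Cth (1.10 ± 0.36) rose (list median 0.04, mean -0.15, camera adjusted p = 0.556). Slc7a5 lost its call in 10 of 16 fits without 1 tumor. The heparan sulfate degrading enzymes Sgsh and Naglu rose, by 1.89 ± 0.31 and 0.78 ± 0.19, and Map1lc3a fell among 37 lysosome and autophagy genes. The club cell mucin gene Muc5b rose by 2.46 ± 0.54, and Sdc1 by 1.21 ± 0.22. Lists with 0 calls included 19 endothelial, 20 fibroblast, 14 ciliated cell, 20 epithelial-mesenchymal transition, 17 immediate early and 35 interferon and antigen presentation genes, with camera adjusted p from 0.115 to 0.959.

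Histone genes with symbols that start with Hist formed the family with the most calls for its size. Of 161 families of gene symbols with at least 10 tested members, Hist had 8 of 14 members lower and 1 higher (exact hypergeometric p = 5.69e-06, adjusted 0.00183). That test, used for each family, treats genes as independent. Members of 1 family can vary together, so its p does not measure the spread between tumors. The lower Hist genes other than Hist1h2bc and Hist1h1c averaged at most 6.38 CPM in wild-type tumors. Hist1h2bc fell most clearly, by 2.67 ± 0.38 (11.1 ± 4.28 against 70.6 ± 44.5 CPM), while Hist4h4 rose by 0.98 ± 0.26. After the length and GC correction 6 were lower, and without wild-type tumors 2, 4 and 7 the only lower call was Hist1h2bc (-2.29). Hist1h2be (-1.84), Hist1h2ac (-1.81), Hist2h3c1 (-1.66) and Hist1h2ae (-1.60) did not pass there. Nor did Hist1h1d (-1.15, from -1.80), Hist1h1e (-1.14, from -1.79) and Hist1h1c (-0.62, from -1.50), which shrank. Lsm genes, for RNA-binding ring proteins, had 6 of 12 lower (adjusted p = 0.0388) and 0 without those tumors. Over the fixed lists, 2 S-phase genes, Rpa2 (-1.03 ± 0.20) and Rfc3 (-0.95 ± 0.22), fell of 38.

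The counts of genes lay far above those of drawn splits of the tumors, and the count of lists did not. Among 100 splits of the 16 tumors into 9 and 7, the real one included, 1 gave as many called genes, the real one with 2378, and the highest of the others gave 1. The same held for genes higher (1 of 100 splits, 1097 against at most 0), lower (1 of 100, 1281 against at most 1) and changed at least 2-fold (1 of 100, 1176 against at most 1). Only 100 of the 11440 splits were taken, so no share below 1 in 100 could be found. The real split also divides the tumors by multiply aligned share, so these counts do not separate the labelled genotype from that library difference. As many lists as the real 7 came from 86 of 100 splits, with up to 18, so list calls at the preset correlation are not evidence of a difference between the groups.

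The rise of Stag3 and Mei1 in tumors labelled null was weighed against library bias, and that of Stag3 also against RNA from germ cells. The smaller of the 2 log2 differences was 4.88 after the length and GC correction and 4.92 without wild-type tumors 2, 4 and 7, close to the 5.04 found with all 16. The rise thus does not rest on those 3 tumors or on a trend with length and GC shared by many genes. Neither fit could decide on other library bias. Both genes were higher in every null tumor than in any wild-type tumor, and the wild-type tumors kept still had higher multiply aligned shares than any null tumor. The germ-cell genes Ddx4, Dazl, Sycp1, Sycp3 and Tex101 had a median in null tumors of 0.666% of the level of Stag3. The highest was Sycp1 at 4.58 CPM, against 198 CPM of Stag3. Germ cells as the source would have to carry Stag3 far above these 5 genes, and no germ-cell sample here gives that ratio. Mei1 averaged only 8.24 CPM in null tumors, not far above Sycp1, so these levels cannot decide on germ cells as its source. As a hypothesis, loss of MAX, which acts with MGA in a complex known to silence germline genes, may release a subset of them; the files hold no test of binding, and Stag3 at 11.9 and 4.72 CPM in wild-type tumors 1 and 7 stays unexplained.

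The lower median of ribosomal protein and respiratory chain genes (-0.71 over both lists) was weighed against library bias. After the length and GC correction it was -0.25, which decides neither way. Without wild-type tumors 2, 4 and 7 it was 0.028, so the pattern rests on those 3 libraries, which carried the highest shares of multiply aligned reads. No fall tied to the genotype is claimed for these genes.

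The lower Mycl in tumors labelled null was weighed against 1 extreme tumor and against copy gain of its region. Without wild-type tumor 1 the log2 difference was -2.01 ± 0.60 (adjusted p = 0.0287; over its alternatives, 0.000236 with DESeq2 to 0.372 with surrogate variables), so that tumor alone is not the cause. Across 16 tumors Mycl followed the mean of its 20 neighbouring genes (Spearman rho = 0.632, permutation p = 0.0099, adjusted over 4 genes 0.04, and Pearson r = 0.757, permutation p = 6e-04, adjusted 0.0024). Without wild-type tumors 1 and 2, whose Mycl lay farthest from its median, r was 0.629. Wild-type tumor 7, with the highest neighbour mean, stayed in, so this value cannot show that the relation holds without it. The relation held in wild-type tumors (rho = 0.821, exact permutation p = 0.0341, and r = 0.764, exact permutation p = 0.0405, n = 7) and less clearly in null tumors (rho = 0.3, exact permutation p = 0.437, and r = 0.252, exact permutation p = 0.503, n = 9). The difference between the groups was not tested. Copy gain in single wild-type tumors is a candidate explanation: the 6 nearest genes, Ppt1, Cap1, Mfsd2a, Trit1, Bmp8b and Ppie, had a median of 3.07, 1.56 and 3.39 log2 units above their own medians in wild-type tumors 1, 6 and 7 (over 1 in 6, 4 and 6 of the 6 genes; Ppt1 and Cap1 were -0.23 and 0.34 in tumor 6), against at most 0.32 in null tumors and 0.72 in the other wild-type tumors. Wild-type tumor 7 also had the highest share of multiply aligned reads (22.2%). These levels carried no length and GC correction, so library bias in that tumor cannot be excluded. An r as high as 0.757 occurred for 3.5% of 14051 genes and for 77 of 1167 lower genes. DNA was not analysed here, and whether Max status alters selection for such a gain stays open.

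Nfib, the other lower oncogene, also followed its 20 neighbours (rho = 0.565, permutation p = 0.024, adjusted 0.048; r = 0.677, permutation p = 0.0038, adjusted 0.0076), with r = 0.447 without the 2 farthest tumors, so the relation leans on those. Within groups Nfib gave rho = 0.821 (exact permutation p = 0.0341) and r = 0.756 (p = 0.0504) in 7 wild-type tumors, and rho = 0.067 (p = 0.88) and r = 0.245 (p = 0.488) in 9 null tumors. An r as high occurred for 7.32% of genes and for 133 of 1167 lower genes. Mycn and Myc did not follow theirs (rho = 0.194 and 0.279, permutation p = 0.47 and 0.29).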
